A study of Mus musculus with 8 samples.

How the data were processed

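The series holds 8 mouse samples from hybrid embryos whose zygotes received mRNA for Kdm6b or a mutant form of it. Kdm6b is a demethylase that removes methyl groups from lysine 27 of histone H3. The measurements were 4 RNA-seq libraries of blastocysts and, in morulae, 2 ultra-low-input native ChIP-seq libraries for H3K27me3 with 2 input libraries. Groups were taken from the sample titles. Other label fields differ from the titles in places: the blastocyst RNA samples also carry a morula tag, and both inputs carry a tag for no injection. Only the ChIP-seq peak lists were analysed here. The RNA-seq libraries were not analysed here.

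Each list holds the peaks of 1 ChIP library called against input. The submitters' processing notes name Bowtie2 2.2.2, MACS2, STAR, featureCounts, Subread 1.5.1 and the build mm9 for the series, without saying which step used which tool. The 9 columns follow the order of a MACS2 broad peak list and have no header. Peak positions were deposited in mm9 coordinates and are given here counted from 1. Each peak has a fold enrichment of ChIP over input, a ratio as deposited by the authors. Each also has a −log10 p and a −log10 q as deposited by the authors. The whole-number score deposited beside them equals 10 times the −log10 q rounded down in 100% of Kdm6bWT peaks and 99.998% of Kdm6bMUT peaks. The highest q among the peaks was 0.0984 in the Kdm6bMUT list and 0.0910 in the Kdm6bWT list. Within a list, neighbouring peaks were never closer than 1201 bases (Kdm6bMUT) or 1205 bases (Kdm6bWT), and no peak was narrower than 300 bases. The caller's settings, duplicate handling and any input scaling are not given in the sources used here. Read depth is unknown, because the lists give no read counts. A peak list moves with depth, since a deeper library lets weaker enrichment pass the same q. Fold enrichments are therefore used only within a list. A p or score limit taken from the Kdm6bWT list was applied to both lists in some alternatives, where the counts that pass still move with depth.

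The number of peaks, their widths and the bases they cover were computed for each list with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. A peak counted as overlapped when it shared at least 1 base with a peak of the other list. Shares of peaks have 95% exact (Clopper-Pearson) binomial intervals. These cover counting error only, and neighbouring peaks are not independent. To show the overlap that position alone would give, the Kdm6bWT list was rotated within each chromosome by a random step, 1000 times with a fixed seed. In a further 1000 draws each Kdm6bWT peak was moved by 20 to 200 kb in a random direction. The length of a chromosome was taken from the first to the last peak on it in either list. Coverage was also summed in windows of 1 Mb. Kdm6bMUT peaks were split at the quartiles of their width and of their score; scores are whole numbers, so ties make the score classes unequal. The overlap code was tested on simulated data: of 1000 peaks planted against the Kdm6bMUT list, 600 inside its peaks and 400 between them, 600 were called overlapped and 180000 shared bases were recovered.

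Each group has 1 ChIP library, so the design has no replicate check. No test between the groups was made and no p-value is given; every comparison is between these 2 libraries. The main measures, the alternatives listed here and the rule for named regions were fixed before the data were examined. The local moves, the comparison of windows and long runs, and some alternative settings were added later. The rule named the 5 windows of 1 Mb most covered in each list, and the 3 widest and 3 highest-scoring peaks of each list. Windows and runs of peaks on X beyond that rule were chosen after their values were seen. Alternatives were a score floor at the Kdm6bWT median of 13, merging of peaks less than 1 kb or 5 kb apart, a minimum width of 1 kb, autosomes alone, an overlap of at least 50% of the peak, lists of equal length and shares of peaks in place of bases.

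The gene annotation used here is for GRCm38, and on 7 of the 20 chromosomes compared the lists hold peaks past its last gene. Coordinates were not converted between builds. Genes were therefore not placed on the peaks, and the gene counts and gene lists planned beforehand were not made.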

Results

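H3K27me3, a histone mark laid down by Polycomb repressive complex 2, was profiled in mouse morulae that developed from zygotes injected with mRNA for Kdm6b (Kdm6bWT) or for a mutant form of it (Kdm6bMUT). The mRNA was injected at 1.8 µg/µl between 2.5 and 4 hours after fertilization. The embryos were labelled as BDF1 × PWK hybrids. One ChIP library per injection was called against input, and all values below compare 1 Kdm6bMUT library with 1 Kdm6bWT library, without replicates. The question set by this design is where H3K27me3 was lost and where it was kept when the demethylase was supplied. The series title names Xist, the X-linked RNA gene that drives X inactivation. No mm9 gene annotation was used here, so neither Xist nor any other gene was placed on the peaks, and regions are named by their mm9 position.

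H3K27me3 peaks were far fewer, narrower and less extensive in Kdm6bWT-injected than in Kdm6bMUT-injected morulae. The Kdm6bMUT list held 90158 peaks that covered 251 Mb, and the Kdm6bWT list held 4991 peaks that covered 3.53 Mb. The ratio of Kdm6bMUT to Kdm6bWT was 18.1 for the number of peaks and 71.0 for the covered bases. The median peak width was 1577 bases (quartiles 781 and 3316) in the Kdm6bMUT list and 493 bases (quartiles 304 and 972) in the Kdm6bWT list. Mean widths were 2781 and 708 bases. Domains of 10 kb or more numbered 3847 in the Kdm6bMUT list, or 4.27% of its peaks, against 2 in the Kdm6bWT list. The smallest width in both lists, 300 bases, was that of 4.19% of Kdm6bMUT peaks and 23.7% of Kdm6bWT peaks. The median fold enrichment over input was 3.07 for Kdm6bMUT peaks and 3.84 for Kdm6bWT peaks. These medians are not comparable between lists, because the weakest accepted peak had a −log10 p of 2.41 in the Kdm6bMUT list and 3.67 in the Kdm6bWT list. At the latter value the Kdm6bMUT list still held 41477 peaks, or 8.31 times the Kdm6bWT number. The median score was 18 (quartiles 15 and 21) in the Kdm6bMUT list and 13 (quartiles 11 and 16) in the Kdm6bWT list. Read depth is unknown, and a shallower Kdm6bWT library would also give fewer and narrower peaks. The ratio of covered bases was 156 among peaks with a score of at least 13 and 135 among peaks of at least 1 kb.

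The 1 Mb windows with the most H3K27me3 peak coverage in Kdm6bMUT-injected morulae held far less in Kdm6bWT-injected morulae, though more than most autosomal windows of the Kdm6bWT list. The most covered 1 Mb window lay on chromosome 12 between 108 and 109 Mb, where Kdm6bMUT peaks covered 774 kb and Kdm6bWT peaks 4.53 kb. In the window from 143 to 144 Mb on chromosome 7 the covered lengths were 731 kb and 2.75 kb. On chromosome 14, between 117 and 118 Mb, they were 664 kb and 4.24 kb. The window from 49 to 50 Mb on chromosome 17 had 645 kb and 2.65 kb, and that from 112 to 113 Mb on chromosome 9 had 611 kb and 2.04 kb. Kdm6bWT peaks held between 0.333% and 0.525% of the Kdm6bMUT bases in these 5 windows, each below the 0.591% of the autosomes together. The windows were chosen for high Kdm6bMUT coverage, the denominator of this share, which tends to lower it, so no stronger loss is read from it. By length, Kdm6bWT peaks covered 0.204% to 0.453% of each window, against 0.140% of the autosomes together. Each window also lay above the upper quartile of Kdm6bWT coverage over autosomal windows, 1.92 kb. The widest single Kdm6bMUT peak spanned 91.8 kb on chromosome 6 (118965425 to 119057236), of which 2.05 kb lay in Kdm6bWT peaks. The next widest, 78.8 kb on chromosome 13 (42789406 to 42868213), contained no Kdm6bWT peak. The third, 78.7 kb on chromosome 7 (124604606 to 124683281), had 1.29 kb in Kdm6bWT peaks.

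Of the 90158 Kdm6bMUT peaks, 2400 touched a Kdm6bWT peak, a share of 2.66% (95% exact interval 2.56% to 2.77%). Kdm6bWT peaks held 0.604% of the Kdm6bMUT bases. Conversely, 2470 of the 4991 Kdm6bWT peaks lay on Kdm6bMUT peaks, a share of 49.5% (48.1% to 50.9%), and 2521 lay outside them. Rotating the Kdm6bWT list within chromosomes gave a mean share of 12.5% (lowest 10.7%, highest 15.4% of 1000 rotations). Moving each Kdm6bWT peak by 20 to 200 kb, which keeps its region, gave a mean of 26.0% (24.2% to 27.8% in 1000 draws). The observed share was 3.96 times the mean of the rotations and 1.91 times that of the local moves. Kdm6bWT peaks on Kdm6bMUT domains had a median width of 586 bases, against 433 bases for those outside. Both sets had a median fold enrichment of 3.84, and the widths were not compared with those of moved peaks. Of the 4991 highest-scoring Kdm6bMUT peaks, 3.51% touched a Kdm6bWT peak. The share of Kdm6bWT peaks that touched this shorter list was 3.59%, which is lower by construction. The share of Kdm6bMUT peaks touched ranged from 0.243% to 7.22% with the overlap, score, width and merging used.

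Wide Kdm6bMUT domains were touched by a Kdm6bWT peak more often than narrow ones, and the difference was smaller per base. The share touched was 0.705% (95% exact interval 0.600% to 0.824%) in the narrowest quartile, of up to 781 bases. It was 6.73% (6.40% to 7.06%) in the widest, of 3316 bases or more, a ratio of 9.53. Counted per base, the shares were 0.449% and 0.666%, a ratio of 1.48. The widest quartile held 64.6% of all Kdm6bMUT bases. The order of the quartiles relative to moved peaks depended on how the peaks were moved. The narrowest quartile was touched 2.98 times and the widest 4.40 times as often as the mean of the rotations, but 2.10 and 1.82 times as often as the mean of the local moves. Split at the quartiles of the score, 1.16% (1.04% to 1.30%) of the Kdm6bMUT peaks with scores of 10 to 15 were touched, and 4.54% (4.23% to 4.86%) of those with scores of 22 or more. The shares of bases in Kdm6bWT peaks were 0.385% and 0.761%.

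**Figure D1:**
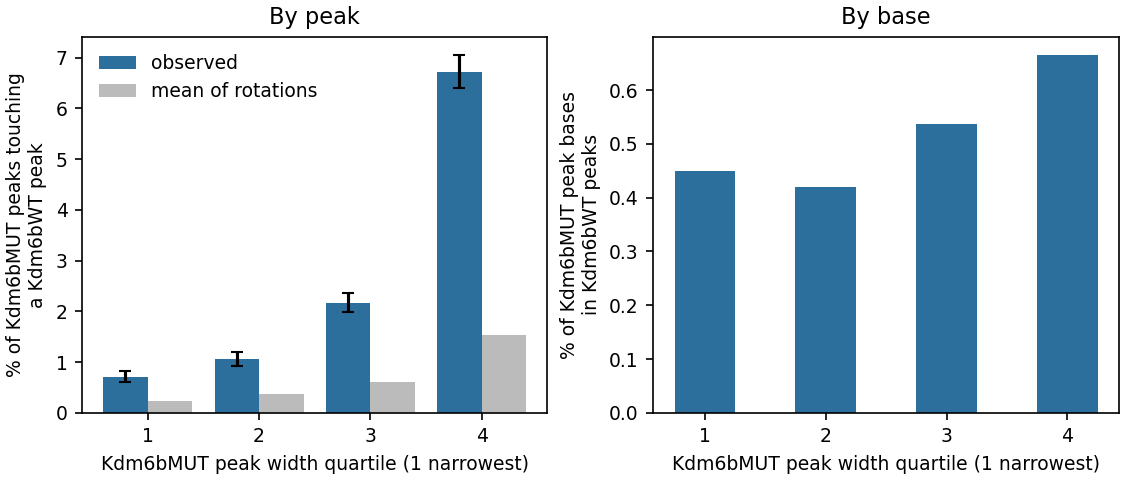
Kdm6bMUT peaks by width quartile (x axis): left, the percentage of peaks that touch a Kdm6bWT peak, with 95% exact intervals as error bars and the mean of 1000 rotations in grey; right, the percentage of their bases inside Kdm6bWT peaks. The share rises from 0.705% to 6.73% by peak and from 0.449% to 0.666% by base between the narrowest and the widest quartile.

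The X chromosome carried far less H3K27me3 peak coverage than the autosomes in Kdm6bMUT-injected morulae. Kdm6bMUT peaks covered 1.97% of X, whereas they covered between 5.84% (chromosome 19) and 12.5% (chromosome 17) of each autosome, and 10.3% of the 19 autosomes together. X held 1307 Kdm6bMUT peaks, 1.45% of the list (95% exact interval 1.37% to 1.53%), although it makes up 6.29% of the length compared. Kdm6bWT peaks covered 0.0868% of X and between 0.111% and 0.216% of each autosome. X held 190 Kdm6bWT peaks, 3.81% of that list (3.29% to 4.38%). The density of peaks on X relative to autosomes was 0.219 (0.208 to 0.232) in the Kdm6bMUT list and 0.591 (0.509 to 0.684) in the Kdm6bWT list. No peak of either list lay on the Y chromosome.

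A larger part of the Kdm6bMUT coverage lay in Kdm6bWT peaks on X than on any autosome. The ratio of Kdm6bMUT to Kdm6bWT covered bases was 22.8 on X, against 46.6 (chromosome 19) to 94.8 on single autosomes and 73.3 over all of them. Kdm6bWT peaks held 1.47% of the Kdm6bMUT bases on X, 0.591% of those on the autosomes together, and between 0.445% and 0.696% on each autosome. By number, 58 of the 1307 X peaks were touched (4.44%, 95% exact interval 3.39% to 5.70%), against 2.63% (2.53% to 2.74%) of autosomal peaks. Rotated lists gave a mean shared length of 0.0849% on X, with a highest value of 0.602%, and 0.142% on the autosomes. Local moves turned this order, with a mean of 0.557% on X (highest 0.915%) and 0.307% on the autosomes, so position within the same regions alone gave X the higher shared length. The observed length was 17.3 times the mean of the rotations on X and 4.17 times on the autosomes, against 2.63 and 1.93 times the mean of the local moves. From the Kdm6bWT side, 32.6% of X peaks (26.0% to 39.8%) and 50.2% of autosomal peaks (48.7% to 51.6%) lay on Kdm6bMUT peaks. By base, the shares were 33.4% on X and 43.4% on the autosomes. The larger shared part of Kdm6bMUT bases on X thus follows from the lower ratio of covered bases there and is not a separate result. Among peaks with a score of at least 13, the shared length was 0.740% on X and 0.267% on the autosomes.

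**Figure D2:**
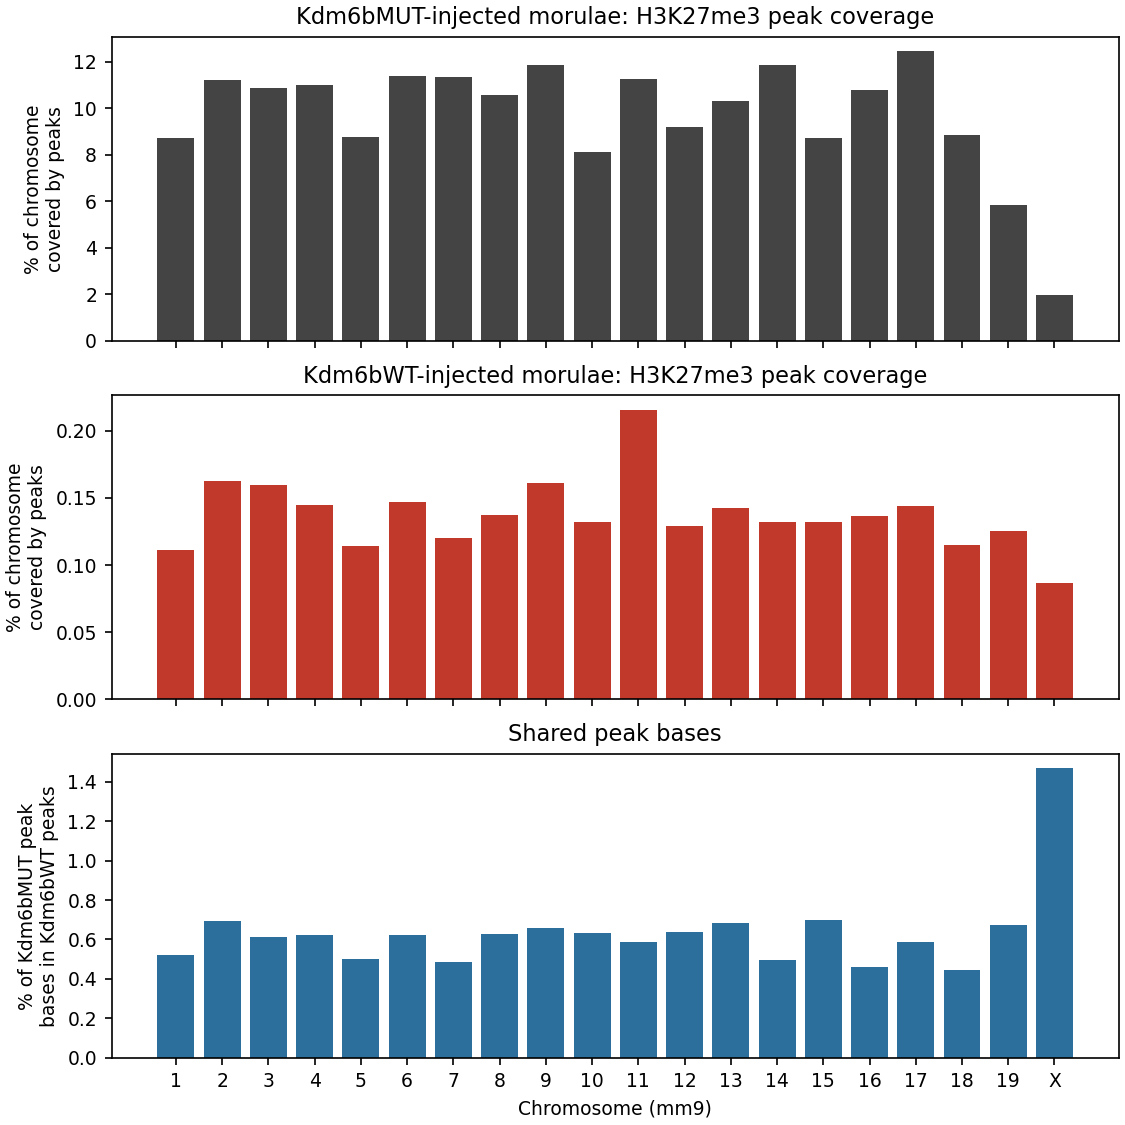
Bars give, for each chromosome (x axis, mm9), the percentage of its length covered by H3K27me3 peaks in the Kdm6bMUT list (top) and the Kdm6bWT list (middle, on a different scale), and the percentage of Kdm6bMUT peak bases that lie in Kdm6bWT peaks (bottom). X has the lowest coverage in both lists (1.97% and 0.0868%) and the highest shared percentage (1.47%).

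Kdm6bMUT peak coverage on X was gathered in a smaller share of windows than on the autosomes. Of its 167 windows of 1 Mb, 73 (43.7%) had no Kdm6bMUT peak coverage, against 10.1% of autosomal windows. The median window had 0.443 kb of coverage on X and 53.6 kb on the autosomes. The 10 most covered X windows held 61.9% of the Kdm6bMUT bases on X, and the same measure ranged from 22.3% to 54.9% on autosomes. In the Kdm6bWT list it was 46.0% on X, within the 21.0% to 51.1% of the autosomes. Windows without a Kdm6bWT peak were 58.1% of those on X and 28.2% of those on the autosomes, with a range of 15.6% to 38.6% over single autosomes. The 5 most covered windows began at 10, 48, 100, 137 and 96 Mb, with 420 kb, 275 kb, 230 kb, 228 kb and 191 kb of Kdm6bMUT coverage. Kdm6bWT peaks covered 5.77 kb, 3.70 kb, 10.3 kb, 7.75 kb and 3.64 kb of them. The window that starts at 100 Mb was the most covered X window of the Kdm6bWT list. It was crossed by a run of 50 Kdm6bMUT peaks, separated by less than 10 kb, that extended for 419 kb from 100658866 to 101078124 and continued into the neighbouring window. Kdm6bMUT peaks filled 66.7% of this run, with fold enrichments between 2.59 and 3.96. In Kdm6bWT-injected morulae 14 peaks lay in the run, 13 of them on Kdm6bMUT peaks. They covered 2.95% of its length and held 4.06% of its Kdm6bMUT bases. X windows and this run were singled out after their values were seen, and the window was picked for its Kdm6bWT coverage.

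**Figure D3:**
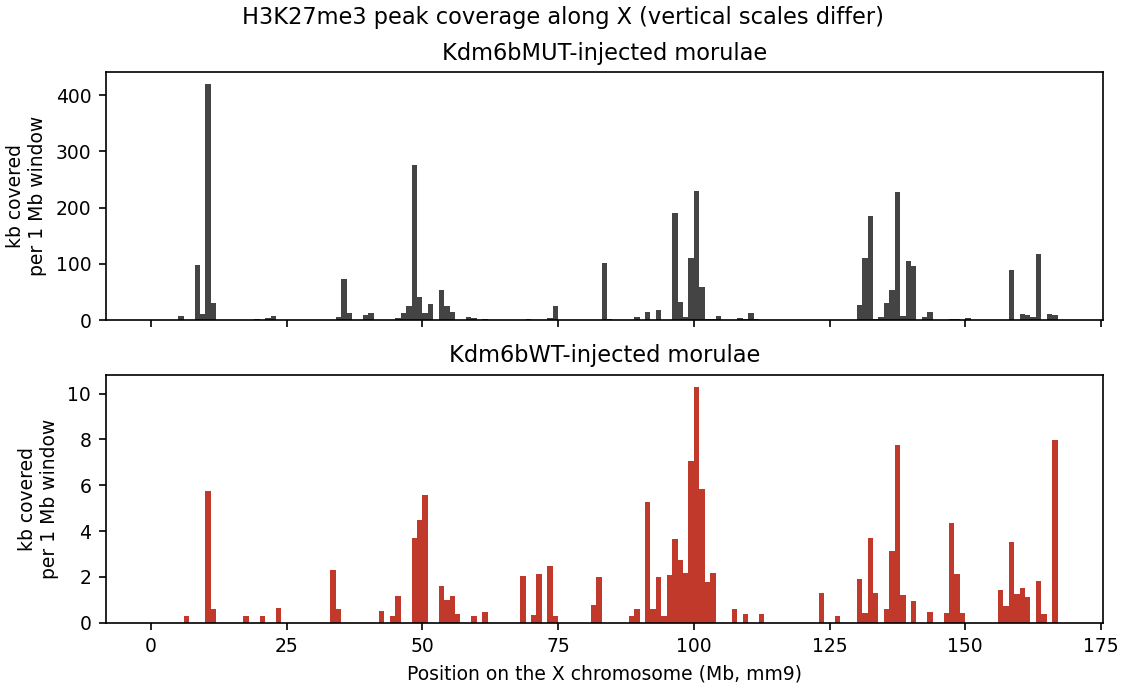
Kilobases covered by H3K27me3 peaks in each 1 Mb window along X (x axis, position in Mb, mm9) in the Kdm6bMUT list (top) and the Kdm6bWT list (bottom, on a different scale). Both lists have high bars in the windows that start at 100 Mb (230 kb and 10.3 kb) and at 137 Mb (228 kb and 7.75 kb).

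**Figure D4:**
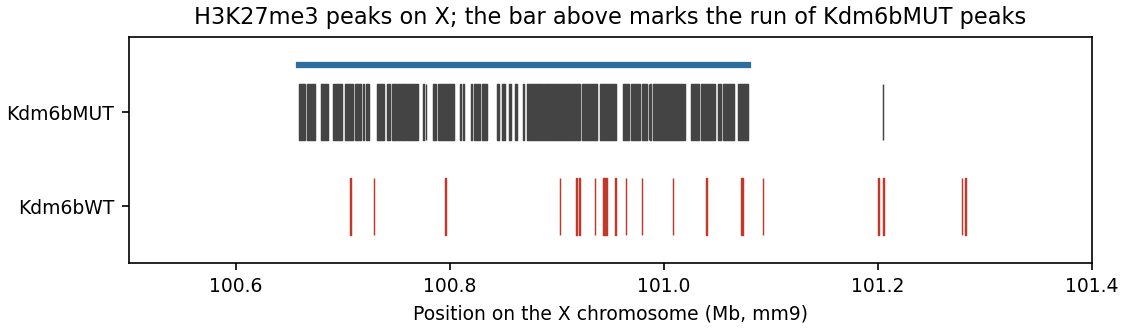
Peaks of the Kdm6bMUT list (grey) and the Kdm6bWT list (red) drawn to scale on X (x axis, position in Mb, mm9), with a thin outline so that the narrowest show. The blue bar marks the 419 kb run, which holds 50 Kdm6bMUT and 14 Kdm6bWT peaks.

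The most covered windows of the Kdm6bWT list included some with little Kdm6bMUT coverage. Near the start of chromosomes 11 and 9, between 3 and 4 Mb, Kdm6bWT peaks covered 55.1 kb and 26.9 kb, more than the 8899 and 19048 bases of the Kdm6bMUT list. The 3 widest Kdm6bWT peaks all lay in that chromosome 11 window, with widths of 13.8 kb (3051173 to 3064940), 12.1 kb (3079697 to 3091822) and 7.88 kb (3066410 to 3074291), and none touched a Kdm6bMUT peak. Their fold enrichments, 2.45, 2.52 and 2.26, lay below the lower quartile of 3.64 for Kdm6bWT peaks. Whether they are H3K27me3 domains or background was not tested. The other 3 windows were dense in both lists. They were chromosome 3 from 51 to 52 Mb (15.7 kb against 430 kb in Kdm6bMUT), chromosome 8 from 60 to 61 Mb (13.4 kb against 456 kb) and chromosome 11 from 57 to 58 Mb (12.8 kb against 250 kb).

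In the Kdm6bMUT list the 3 peaks with the highest scores lay on chromosome 9 (35112689 to 35113257, score 308), chromosome 3 (35579235 to 35580035, score 249) and chromosome 6 (103598915 to 103601279, score 209). All 3 touched a Kdm6bWT peak. The chromosome 9 peak had a fold enrichment of 2.79, below the lower quartile of 2.87 for Kdm6bMUT peaks, despite its score. Those on chromosomes 3 and 6 had 4.64 and 3.55, above the upper quartile of 3.29. Whether the highest-scoring sites of either list are H3K27me3 or sites that attract reads in any library was not tested. In the Kdm6bWT list the highest score, 1379, belonged to a peak of 762 bases on chromosome 17 (4625997 to 4626758) with a fold enrichment of 49.5. It was followed by the same chromosome 9 site (35112650 to 35113295, score 1023) and by a site on chromosome 12 (3109722 to 3110291, score 686). All 3 touched a Kdm6bMUT peak. Among the 20 highest-scoring peaks, 14 of the Kdm6bWT list (70.0%, 95% exact interval 45.7% to 88.1%) and 13 of the Kdm6bMUT list (65.0%, 40.8% to 84.6%) touched a peak of the other list. The 49.5% of the whole Kdm6bWT list lies inside the first interval, and among the 251 Kdm6bWT peaks in the top 5% by score the share was 46.6% (40.3% to 53.0%), so a higher share at high Kdm6bWT scores was not shown.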

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

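One result came from sequence outside the autosomes and X, which the comparisons by chromosome do not use. The Kdm6bWT list held 2 peaks on the mitochondrial genome that covered 9858 of its bases, with fold enrichments of 2.06 and 2.08, and the Kdm6bMUT list held 0. Sequences that are unplaced, or not ordered on a chromosome, held 47 Kdm6bMUT peaks, of which 6 were shared. The Kdm6bWT list had 13 peaks outside the autosomes and X, the mitochondrial ones included, of which 6 were shared.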

How the results depend on the processing

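No paired analysis was possible because each injection has 1 ChIP library, and depth, which sets how many peaks a list can hold, is unknown. Of 35 values from alternative settings, 12 stayed within 1.5 times the reported value (counts and the ratio of covered bases) or inside a 95% exact interval over the number of peaks (shares), and 23 did not. The floors, minimum width and shortened list leave fewer peaks by construction, and otherwise the cause was not tested. Kdm6bMUT coverage exceeded Kdm6bWT coverage by 71.0 to 156 times in all settings that gave this ratio. The score floor kept 86917 of 90158 Kdm6bMUT peaks but 2592 of 4991 Kdm6bWT peaks, which favours a high ratio. The ratio was not taken at the p limit of the Kdm6bWT list, so 71.0 is not a tested lower bound. With a score floor of 13 the Kdm6bWT list held 2592 peaks, the ratio of covered bases was 156, the shares of peaks overlapped were 1.41% (Kdm6bMUT) and 47.8% (Kdm6bWT), and the shared bases were 0.740% on X and 0.267% on autosomes. Merging peaks less than 5 kb apart left 30698 Kdm6bMUT peaks and gave shares of 7.22% and 58.2%, while merging below 1 kb joined none. Peaks of 1 kb or more numbered 1198 in the Kdm6bWT list, with a ratio of covered bases of 135 and shares of 1.04% and 53.3%. Requiring 50% of a peak to be covered gave 0.243% and 41.5%, and lists of equal length gave 3.51% and 3.59%. The X share of the Kdm6bMUT list was 1.45% by peaks in place of 1.27% by bases. The following settings were chosen after seeing the data. At the lowest p of the Kdm6bWT list, 41477 Kdm6bMUT peaks remained. Without the 5 most covered X windows, X held 0.743% of Kdm6bMUT bases and 3.11% of Kdm6bWT bases. Counted by base, the overlapped shares were 0.604% and 42.9%. Gene-based alternatives were not run, since no gene was placed.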

Other observations

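The test of local moves was set before its result was seen, and the other tests were chosen after the results they bear on. Kdm6bWT peaks outside Kdm6bMUT domains were often close to one: 41.5% of the 2521 lay within 5 kb of a Kdm6bMUT peak, against a mean of 16.2% in rotated lists and 27.2% after moves of 20 to 200 kb. Across 1 Mb windows the coverage of the lists had a Spearman correlation of 0.55 over 2479 autosomal windows and 0.45 over 167 X windows. Windows are not independent replicates, and no p-value is given. Among the 10 most covered X windows of each list, 4 were in common, where 0.599 would be shared by chance.

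Long runs of Kdm6bMUT peaks differed in how much Kdm6bWT coverage they held. Joined across gaps of less than 10 kb, 386 runs reached 200 kb, 4 of them on X. The median run had 0.487% of its Kdm6bMUT bases in Kdm6bWT peaks (quartiles 0.136% and 0.923%), and 86 runs had none. The X run from 100658866 to 101078124 had 4.06%, which ranked 2 among the 386, but it had been picked for the Kdm6bWT coverage of its window. The highest, 4.74%, was on chromosome 8 (83287460 to 83497495), followed after the X run by runs on chromosome 6 (37196249 to 37418392, 3.70%) and chromosome 11 (57404511 to 57609216, 3.58%).

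The first pattern weighed is the short Kdm6bWT list. A stricter p threshold alone is argued against, because 41477 Kdm6bMUT peaks pass the lowest p of the Kdm6bWT list, 8.31 times its 4991. A lower depth of the Kdm6bWT library would place its peaks mostly inside Kdm6bMUT domains and at the strongest of them. The share of Kdm6bMUT peaks touched was 1.16% in the lowest score class and 4.54% in the highest, against 2.66% overall. Per base, these classes had 0.385% and 0.761%. The rise with score was not steady: 3.51% of the 4991 highest-scoring Kdm6bMUT peaks were touched, and 65.0% of the top 20. Against depth alone, 50.5% of Kdm6bWT peaks lay outside in a list whose highest q was 0.0910, but it stays open, because the q rests on the caller's noise model, a Kdm6bWT peak could lie on Kdm6bMUT signal too weak to be called, and the lists hold no read totals. Removal of H3K27me3 by the injected demethylase, which the design names, is also open, and 1 library per group cannot tell it apart from depth.

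The second pattern is the low share of X in the Kdm6bMUT list. Sequence on X where reads cannot be placed would lower both lists alike, but the density of peaks on X against autosomes was 0.219 in the Kdm6bMUT list, below the 95% exact interval of the Kdm6bWT list (0.509 to 0.684), which argues against that as the whole cause. A lower copy number of X, if the pools held embryos of both sexes, may reduce the number of X peaks that pass the threshold. It stays open, since the median fold of X peaks (3.05, against 3.07 on autosomes) covers only peaks that passed and the lists hold no input coverage. A true difference in H3K27me3 between X and autosomes was not tested separately.

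The third pattern is that Kdm6bWT peaks fall on Kdm6bMUT domains more often than rotated ones (49.5% against 12.5%). A broad regional density common to both lists accounts for part of it at most: moving each peak by 20 to 200 kb gave 26.0% on average and 27.8% at the highest of 1000 draws. Density shared over less than 20 kb stays open, because every move was at least that long. Very high-scoring regions found in both lists stay open. Without the 251 Kdm6bWT peaks in the top 5% by score, 49.6% of the other 4740 lay on Kdm6bMUT peaks. Rotations of these 4740 gave a mean of 12.5% and a highest value of 16.3%. Leaving out 251 peaks could not bring the share near the rotations, because 2470 Kdm6bWT peaks lay on Kdm6bMUT peaks. By number, the 251 cannot be most of the overlap, but regions with scores below the top 5% were not examined. Of the 251, 46.6% (95% exact interval 40.3% to 53.0%) lay on Kdm6bMUT peaks, and the 49.6% of the rest lies inside that interval. The hypothesis that part of the Kdm6bWT list is H3K27me3 left in place at Kdm6bMUT domains is consistent with these values, and sites that attract reads in any library were not tested otherwise.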
